A study of Mus musculus with 10 samples.

How the data were processed

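Gene expression was measured on 10 Affymetrix GeneChip mouse arrays, each hybridised with biotin-labelled cRNA made from the total RNA of 1 sample. Per the labels, 8 arrays came from mouse embryonic fibroblasts (MEFs) at day 3 after transduction with pMXs retroviruses, and 2 came from induced pluripotent stem cell (iPSC) clones, clone 3 and clone 4, derived with OSKM plus Jarid2. OSKM stands for the reprogramming factors Oct4 (gene Pou5f1), Sox2, Klf4 and c-Myc. All cells carried a Nanog reporter transgene. The virus was removed after a day, and the MEFs were then kept in embryonic stem cell medium. That medium held leukemia inhibitory factor, the GSK3 inhibitor CHIR99021 and the MEK inhibitor PD0325901. RNA was extracted with either of 2 commercial kits, and the labels do not say which kit served which sample.

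The deposited values are on a log2 scale, 1 per probe set and array. Per the submitters' processing notes they were made with RMA, which corrects background, normalizes quantiles between arrays and summarises the probes of a probe set. Its version and any later step are not given in the sources used here. The log2 scale was read from the values themselves, whose medians lay between 5.179 and 5.278 on the 10 arrays. No value was rescaled or floored. The number of arrays limits the precision: 8 of the 9 groups have 1 array.

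The table held 45101 probe sets. The platform annotation had an entry for 35890 of them and none for 9211, which were left unnamed. Another 932 named several genes and were not used for any gene. After control probe sets were set aside, 34945 probe sets had 1 gene, of which 34741 matched a gene of the mouse RefSeq table (assembly GRCm38.p6) by identifier, and no symbol needed an update. For each of the 18193 genes the probe set with the highest mean over the 10 arrays was used. This choice affected the 9010 genes with more than 1 probe set.

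Groups were taken from the labels. The 4 MEF arrays without OSKM (empty vector, Jarid2, c-Myc, and c-Myc with Jarid2) and the 4 with OSKM (with empty vector, with a mutant of Jarid2, with PrEsS, and with both) each form a factorial set. PrEsS denotes Prdm14, Esrrb and Sall4a together. The labels name the mutant J2deltaC, and without PrEsS it was given together with empty vector. The effects of Jarid2, c-Myc, the Jarid2 mutant and PrEsS were estimated with limma in 1 additive model of the 8 MEF arrays, with a term for each factor and 1 for the set. Each effect is then the mean of its log2 differences in 2 backgrounds. The spread comes from how far these differences depart from each other, with 2 residual degrees of freedom, a prior of 4.9 degrees of freedom and a prior SD of 0.134. The iPSC clones were compared with the empty-vector array in a separate limma fit with 1 residual degree of freedom, a prior of 4.27 degrees of freedom and a prior SD of 0.138. In the fits that leave out a MEF array, the set that lost it gives no spread: its effects are then 1 array against 1, and the spread of the other set is assumed to hold for them. In the iPSC fit the lone MEF array is assumed to vary like the clones. The p-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. Comparisons of 1 array with 1 array (OSKM with empty vector, the combined mix with OSKM alone, and the departures from additivity) have no replicate check and no p-value, and their genes were counted at a size threshold of 2-fold. For each factor, genes at least 1.5-fold apart in the same direction in both backgrounds were also counted. That count is set beside the overlap of independent lists, the product of both counts divided by the number of genes. The origin of the 2 clones and of the MEFs is not given in the sources used here beyond the labels above, so the p-values measure only the spread between these samples.

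Gene lists, 29 in number with 531 listed names of which 495 were measured, were fixed before the data were examined. So were the groups, tests, thresholds and most of the alternatives. They cover core and naive pluripotency, early epithelial genes, mesenchymal regulators, fibroblast identity and extracellular matrix, contractile genes, cell cycle, p53 and senescence, and ribosome biogenesis with Myc-linked growth genes. They also cover glycolysis, oxidative phosphorylation, the Polycomb repressive complex PRC2, developmental regulators bound by Polycomb, and markers of endoderm, mesendoderm, neural cells and the germline. Further lists hold DNA methylation enzymes, interferon response, inflammatory genes, Wnt targets, ERK feedback genes, cholesterol biosynthesis, markers of 6 other cell types (keratinocytes, macrophages and blood, endothelium, skeletal muscle, adipocytes, trophoblast) and the transgenes. For each list the median log2 difference was taken, with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these arrays only. Where a test existed, calls were counted over all genes and adjusted over the list alone.

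Genes at least 4-fold higher in both clones than in the empty-vector array (915, called iPSC-high) or at least 4-fold lower (1429, called MEF-high) were followed through the MEF arrays. These sets were chosen with the empty-vector array, which is also the reference of some differences. Simulated unchanged arrays set against it gave medians of 0.02 for iPSC-high and -0.01 for MEF-high genes.

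Named genes follow a rule set beforehand. For each comparison it takes every probe set of the transgenes, the 10 genes with the highest and the 10 with the lowest log2 difference, and up to 4 members of each list with the largest difference. Factor effects were ranked by the smaller of their 2 background differences, and iPSC differences by the smaller of the 2 clones'. Predicted genes and those without a proper symbol were passed over.

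The limma step was tested on simulated data for the 18193 genes, with 100 genes changed 2-fold and 100 changed 4-fold in each of 20 draws. In the additive model a mean of 98.8% to 99.0% of the 2-fold changes was recovered, depending on the factor. The mean number of unchanged genes called was 25.4 for Jarid2, 23.2 for c-Myc, 24.8 for the Jarid2 mutant and 24.3 for PrEsS. Their share of the calls averaged 11.3%, 10.4%, 11.0% and 10.8%, above the 5% that the adjustment aims at. In the iPSC fit 98.2% of the 2-fold changes were recovered, and unchanged genes made up 19.9% of the calls. Under this simulation, adjusted p-values close to the threshold are too small in both designs. It drew independent noise with the same spread in both sets and changed only 200 of the 18193 genes. These shares therefore do not carry over to the real calls.

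The 3′ and 5′ control probe sets of beta-actin, Gapdh and 18S rRNA were compared within each array as a check of RNA integrity and labelling. The alternatives tried were another quantile normalization, centring each array on its median, leaving out dim genes (13250 kept, at a log2 floor of 5.21), the mean of a gene's probe sets, every probe set on its own, limma with a trended prior, fits on all 10 arrays or on the 4 arrays of a set, leaving out each array in turn, and other fold thresholds. The floor is the median of all values in the table and not a measured background. Alternatives chosen after seeing the data were other reference arrays for the iPSC clones, another reference for choosing the iPSC-high and MEF-high genes, and the reading of the fits without the OSKM-alone array as a correction for RNA integrity. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.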

Results

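Genome-wide expression was measured in 8 samples of mouse embryonic fibroblasts (MEFs) at day 3 after retroviral transduction and in 2 iPSC clones. The fibroblast samples fall into a set of 4 without the reprogramming factors OSKM and a set of 4 with them. In the first set the viruses carried no gene (empty vector), Jarid2, c-Myc, or both. Jarid2 is a DNA-binding partner of the Polycomb repressive complex PRC2, which methylates histone H3 at silenced developmental genes. In the second set OSKM came with empty vector, with a mutant of Jarid2 and empty vector, with PrEsS, or with the mutant and PrEsS. PrEsS stands for Prdm14, Esrrb and Sall4a, transcription regulators of pluripotent cells. The label of the mutant, J2deltaC, reads as a deletion at the C-terminus. Both iPSC clones had been derived with OSKM plus Jarid2. Each fibroblast mix was measured on 1 array, so single-array values have no error of their own. Values are log2 expression levels, and differences are log2 differences unless stated otherwise. The iPSC clones correlated at 0.994 over all probe sets, the empty-vector and Jarid2 arrays at 0.997, and either clone with the empty-vector array at 0.845 to 0.846.

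Several of the transduced genes were visible on the arrays. Pou5f1, which encodes Oct4, stood at 3.12 with empty vector, between 8.66 and 9.51 on the 4 arrays with OSKM, and at 12.28 and 12.36 in the iPSC clones. One Jarid2 probe set stood at 6.06 with empty vector and 9.77 with Jarid2, and at 6.39 with c-Myc and 9.19 with both, while the other 2 read 7.49 and 7.59, and 7.72 and 7.57, with empty vector and Jarid2. The first probe set read 6.15 with OSKM alone and 6.96 with OSKM and the mutant, so the mutant was not told apart from endogenous Jarid2. Whether this probe set lies in the part that the mutant lacks was not tested. Esrrb, an orphan nuclear receptor of naive pluripotency, was at 4.99 with OSKM alone and at 10.14 and 10.35 on the 2 arrays with PrEsS by 1 of its 3 probe sets, and the other 2 read 3.65, 4.66 and 5.01, and 6.49, 7.05 and 6.72. Sall4, a zinc-finger factor of embryonic stem cells, was at 4.21 with OSKM alone and at 6.06 and 6.14 with PrEsS by 1 probe set, and at 4.45, 5.06 and 5.03 by the other. Myc stood at 7.24 with empty vector, 8.36 with c-Myc and 8.53 with OSKM. The probe sets of Sox2 (5.18 with empty vector, 5.47 with OSKM), Klf4 (11.11 and 10.08, and 9.86 and 9.44 by its second probe set) and Prdm14 (3.81 with OSKM, 4.05 with OSKM and PrEsS) showed no clear transgene signal at day 3.

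**Figure D1:**
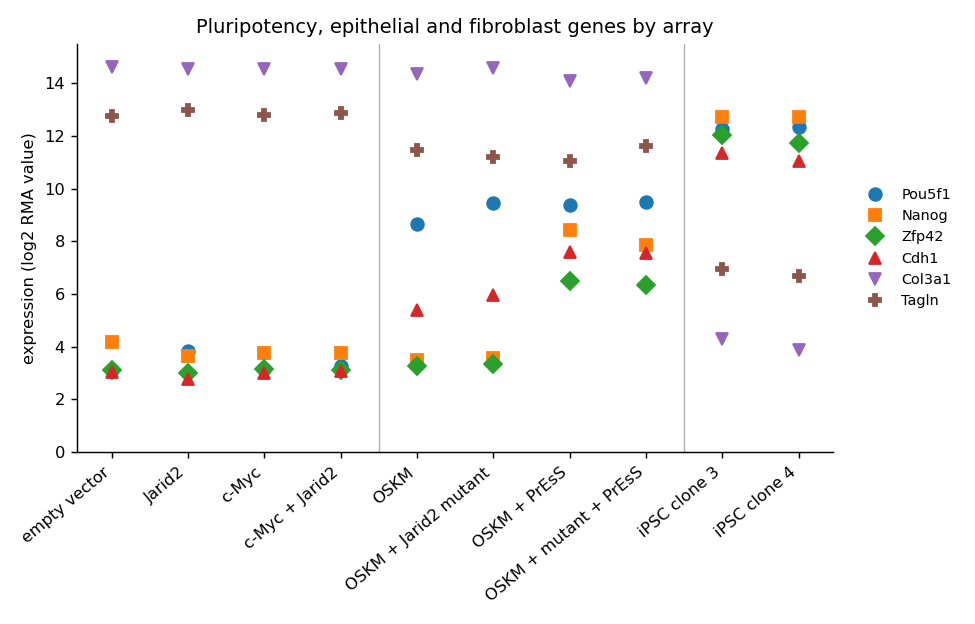
Expression (log2 RMA value, vertical axis) of Pou5f1, Nanog, Zfp42, Cdh1, Col3a1 and Tagln on each of the 10 arrays (horizontal axis), 1 point per gene and array. Nanog lay at 3.48 with OSKM alone, at 8.45 and 7.88 with PrEsS, and at 12.74 in both iPSC clones.

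The arrays also differed in a technical measure. For beta-actin, the 3′ control probe set exceeded the 5′ one by 0.57 to 0.67 on the 4 arrays without OSKM and on the OSKM-alone array, by 1.06 to 1.13 on the 3 other OSKM arrays, and by 1.28 and 1.30 in the iPSC clones. Gapdh split the arrays in the same way, at 0.02 to 0.12 against 0.21 to 0.25. For 18S rRNA the 3 OSKM arrays (-0.70 to -0.57) lay between the 5 arrays (-1.67 to -1.49) and the clones (-0.01 and 0.07), so their place beside the clones is less clear than their distance from the other MEF arrays. Such differences are used to judge RNA integrity and labelling. OSKM alone therefore lies apart from the other 3 OSKM arrays in this measure, so pairs within a side are told apart from pairs across it. Within-side pairs are the combined mix against OSKM with PrEsS, the combined mix against OSKM with the mutant, OSKM alone against empty vector, and all pairs without OSKM.

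**Figure D2:**
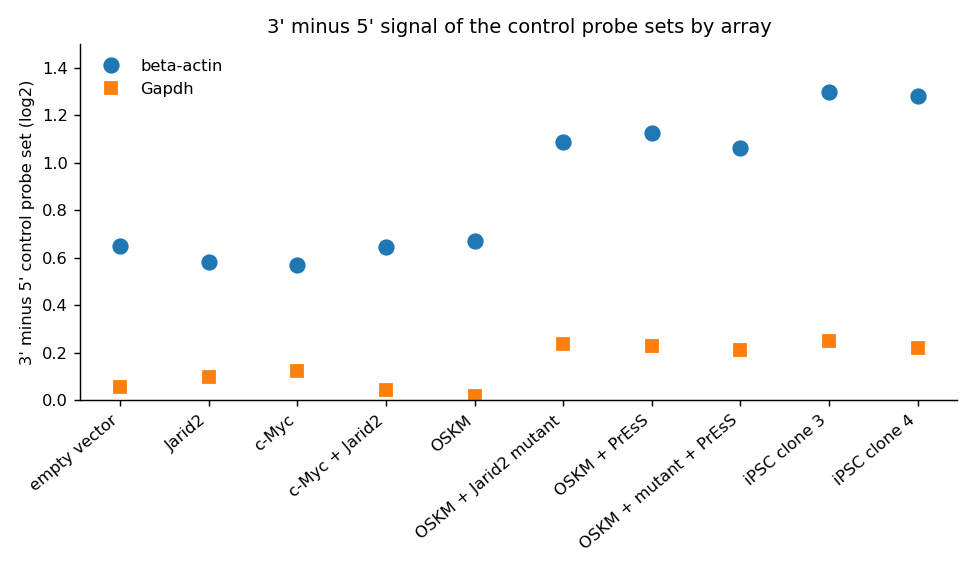
Difference between the 3′ and the 5′ control probe set (log2, vertical axis) for beta-actin (circles) and Gapdh (squares) on each of the 10 arrays (horizontal axis). Beta-actin lies at or below 0.67 on 5 arrays and at or above 1.06 on the other 5.

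The iPSC clones against empty-vector MEFs show how far apart the start and the end of reprogramming lie. All 35 measured members of the pluripotency list rose in the clones, by a median of 5.83. Pou5f1 was up by 9.20 (SE 0.155), the stem cell marker Zfp42 (Rex1) by 8.77, the homeobox factor Nanog by 8.55, the Nodal co-receptor Tdgf1 by 8.53 and Dppa5a by 8.28. Genes of connective tissue were among those with the largest falls: the collagen Col3a1 dropped by 10.51 (SE 0.217) and the matrix protein Postn by 10.24. The mesenchymal cadherin Cdh11 dropped by 10.24 and the collagen cross-linking enzyme Lox by 9.38. These genes passed the test with limma, Benjamini-Hochberg adjusted p between 1.38e-05 and 1.98e-05 (2 clones and 1 array), in both clones alike. The spread is that of the 2 clones alone, so neither these calls nor the counts per list below take in any variation between MEF cultures. Log2 values under 5.21, the median of all values in the table, were taken as near background, and background itself was not measured. Pou5f1 (3.12) lay under that median with empty vector and Col3a1 (4.31 and 3.89) in the clones. Col3a1 in the MEFs (14.61) is close to the highest value of that array (14.65). The sizes of such differences may therefore be lower bounds, and their order is uncertain. Other genes with the largest gains were the epithelial cadherin Cdh1 (8.17), Upp1 (7.84), Dppa2 (7.89), Nr0b1 (7.82) and the muscle fusion peptide gene Mymx (7.71). Prss23 (-9.72), the calcification inhibitor Mgp (-9.60), Ptn (-9.64), Ccn3 (-9.53), the proteoglycan Lum (-9.51) and the chemokine Cxcl5 (-9.51) were among the largest losses.

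Of the fibroblast and matrix list, 24 of 25 genes fell with a median of -6.99, as did 18 of 20 mesenchymal regulators (median -3.64), among them the homeobox gene Prrx1 (-8.41) and the TGF-beta receptor Tgfbr2 (-7.44). In the contractile list 13 of 14 fell and 1 rose (median -4.53, Myl9 -7.61, Acta2 -7.22). Of 25 epithelial genes 17 rose and none fell (median 1.42), with Spint1 up by 5.42 and Cldn4 by 4.89. These 4 counts were the same adjusted over the list alone. Proliferation and growth genes were higher: 24 of 26 cell cycle genes rose and 1 fell (25 and 1 adjusted over the list alone), 24 of 28 ribosome biogenesis genes rose, and all 13 glycolysis genes rose (both the same adjusted over the list alone). Examples are the DNA repair gene Brca1 (4.16), the licensing factor Cdc6 (3.98), the transferrin receptor Tfrc (5.50) and hexokinase Hk2 (4.01). In oxidative phosphorylation 9 of 17 rose and 1 fell, in both counts. Of the DNA methylation enzymes 8 of 10 rose and 1 fell (Tet1 5.99, Dnmt3b 5.85), and 7 of 11 PRC2 genes rose (Jarid2 4.59, the methyltransferase Ezh2 3.39), each the same adjusted over the list alone.

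Developmental regulators bound by Polycomb went down: 31 of 45 fell and 2 rose, with a median of -1.28 (Lhx9 -6.11, Hoxc8 -6.08). Germline genes went up, 11 of 15 (Rhox5 6.14, Dazl 5.96). Endoderm markers split into 5 up and 5 down of 15, mesendoderm markers into 2 up of 11 (Otx2 4.90, Eomes 3.03), and neural markers into 1 up and 4 down of 11. Adjusted over the list alone, these 5 counts did not differ. Interferon genes fell (19 of 22 down and 1 up; 20 and 1 adjusted over the list alone; median -3.0, Ifit1 -6.69). Of 19 inflammatory genes 14 fell and none rose (14 and 1 adjusted over the list alone; Mmp13 -6.92). In the p53 and senescence list 8 of 15 fell and 3 rose (8 and 5 adjusted over the list alone), the largest falls being those of the cell cycle inhibitors Cdkn2a (-6.03) and Cdkn2b (-4.71). Cdkn2a was also lower on the 3 OSKM arrays across the 3′ to 5′ split (7.38 to 7.42, against 11.13 with empty vector). Its fall in the clones is therefore not fully told apart from that split. Wnt targets split into 6 up and 3 down of 14, ERK feedback genes into 5 and 5 of 15 (Egr1 -6.14, Etv5 3.5), in both counts. Cholesterol biosynthesis genes split into 6 up and 2 down of 13 (7 and 2 adjusted over the list alone).

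Markers of other cell types moved less uniformly between clones and MEFs. Of 15 macrophage and blood genes 6 fell and 1 rose, of 10 endothelial genes 3 rose and 2 fell, of 6 adipocyte genes 4 fell and of 9 trophoblast genes 3 rose and 2 fell, the same adjusted over the list alone. For keratinocytes 3 of 13 rose (0 adjusted over the list alone), and for skeletal muscle 3 of 14 rose and 3 fell (1 and 1 adjusted over the list alone). Of the 8 genes carried by any of the viruses 7 rose, in both counts. Prdm14, Esrrb and Sall4 were not in the mix that gave the clones, and viral and endogenous transcripts were not told apart. By limma, 8979 of 18193 genes differed between clones and empty-vector MEFs (4575 up, 4404 down, Benjamini-Hochberg adjusted p under 0.05), and 5888 differed at least 2-fold. Between the 2 clones 21 genes differed at least 2-fold. The comparison crosses the 3′ to 5′ split: against the OSKM and Jarid2 mutant array, which lies nearer the clones in that measure, 5267 genes were at least 2-fold apart, and against OSKM alone, across the split, 5130. The control probe set BioB-3 read 8.85 and 8.80 in the clones, 7.84 with empty vector and 7.95 with OSKM and the mutant. By that probe set neither MEF array lies near the clones. All BioB, BioC, Dap, Lys, Phe and Thr control probe sets were higher in both clones than on each MEF array. This technical difference coincides with that between clones and MEFs, so the calls and list counts of this comparison are confounded with it. Which of them it affects was not tested. With 1 MEF array and 1 residual degree of freedom, the simulated share of unchanged genes among the calls was 19.9%. That simulation changed only 200 genes, so its share does not carry over to the 8979 calls.

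OSKM against empty vector, both on the same side of the split, shows the first 3 days of reprogramming. Most genes with the largest differences were not pluripotency genes: the BMP and Wnt antagonist Sostdc1 was higher by 7.57, the thyroid hormone binding protein gene Crym by 7.43, the aldehyde dehydrogenase Aldh3a1 by 6.95, the secretory granule gene Scg5 by 6.00 and the embryonic globin Hbb-y by 5.23. With empty vector these 5 genes lie near background (Sostdc1 4.24, Crym 3.76), so the differences may be lower bounds and their order is uncertain. Apart from Pou5f1 (5.54), only 3 members of the pluripotency list were at least 1.5-fold higher, L1td1 (4.84), Tfcp2l1 (2.39) and Fbxo15 (1.59), and 5 of its 35 members were lower, such as Klf2 (-1.74). The median of the list was 0.02. Proliferation and growth genes were higher: 24 of 26 cell cycle genes (median 1.07, Aurka 1.52, Mcm6 1.51) and 22 of 28 ribosome biogenesis genes (median 1.00, Tfrc 2.75, the pseudouridine synthase Dkc1 1.69) by at least 1.5-fold, with none lower.

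Genes of the mesenchymal state were lower with OSKM. Of 14 contractile genes 12 were at least 1.5-fold lower (median -1.07, calponin Cnn1 -1.93, Tagln -1.29), as were 11 of 20 mesenchymal regulators (median -0.60, Tgfb3 -1.76) and 15 of 25 matrix genes, with 1 higher (median -0.76, Col5a1 -1.06). Among epithelial genes 5 of 25 were higher, led by the desmosomal protein Dsp (2.84), Cdh1 (2.35) and the keratin Krt19 (1.75). Interferon genes were lower, 15 of 22 (median -0.78, the chemokine Cxcl10 -3.14, Rsad2 -1.68). Higher were 7 of 15 ERK feedback genes (median 0.42, the phosphatases Dusp4 2.01 and Dusp6 1.45) and 5 of 13 glycolysis genes (median 0.44, Pfkp 1.26). Markers of other cells went both ways at 1.5-fold: 2 neural markers were higher (Fabp7 2.68, Tubb3 2.09) and 2 lower, 1 endothelial gene was higher (the receptor Tek, 2.40) and 2 lower, 2 keratinocyte genes were higher (the basal keratin Krt14 1.76) and 0 lower, and of the macrophage and blood genes 0 were higher and 4 lower. The collagen Col8a2 (-3.26), the amine oxidase Aoc3 (-2.54), Sncaip (-2.39), Npr3 (-2.31), C1qtnf3 (-2.29), the tendon gene Tnmd (-2.29) and the cartilage matrix gene Comp (-2.23) were the lowest besides Cxcl10. Between these 2 arrays 544 genes were at least 2-fold higher and 334 lower, against 21 in both directions between the 2 clones. No test applies to 1 array against 1, and the OSKM term of the additive limma model gave 2020 genes at Benjamini-Hochberg adjusted p under 0.05 (1165 up, 855 down). That term also draws on the 3 other OSKM arrays, which lie across the split.

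**Figure D3:**
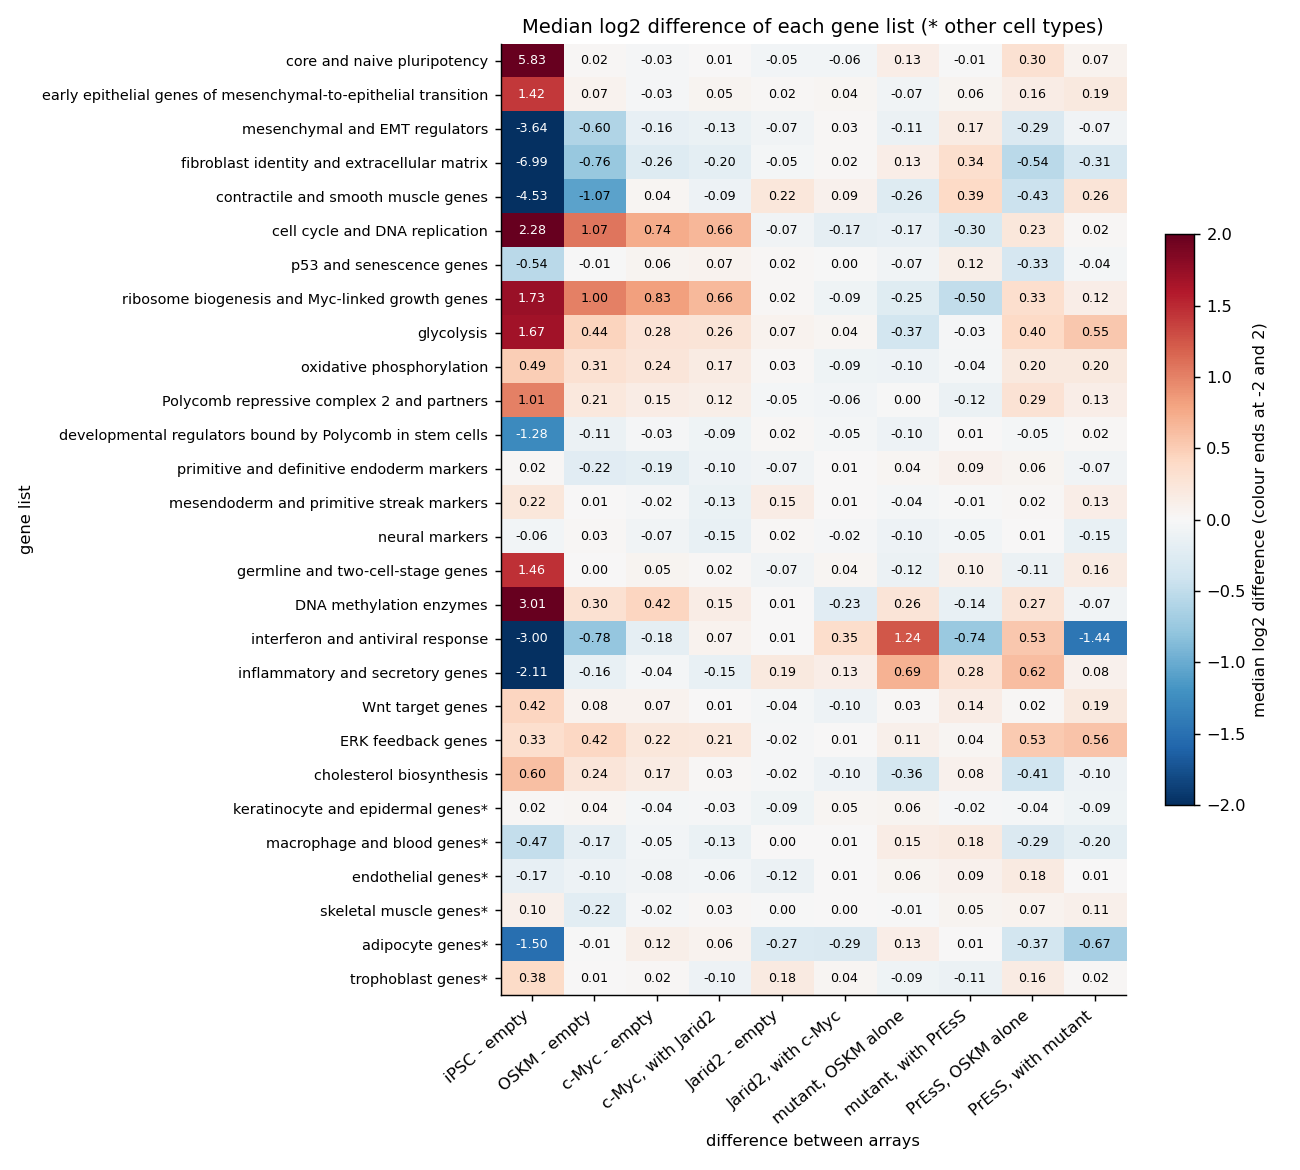
Median log2 difference (colour and printed number) of 28 gene lists (vertical axis) in 10 differences between arrays (horizontal axis), with red for higher and blue for lower. Cell cycle genes have medians of 1.07 with OSKM and of 0.74 and 0.66 with c-Myc, and interferon genes of 1.24 and -0.74 with the Jarid2 mutant.

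With c-Myc and no other OSKM factor, growth and cell cycle genes were higher, with and without Jarid2. Of the 28 ribosome biogenesis genes 17 were at least 1.5-fold higher in both backgrounds (median of the mean effect 0.74), and 13 of the 26 cell cycle genes were (median 0.68). Tfrc was higher by 1.79 alone and 1.59 beside Jarid2, the Myc target Cdca7 by 1.72 and 1.59, the nucleotide hydrolase Dnph1 by 1.33 and 1.32, the deaminase Dctd by 1.41 and 1.29, and Dkc1 by 1.15 and 1.09. The replication licensing genes Mcm5 (0.92 and 0.96) and Cdc6 (1.01 and 0.83) moved likewise. The lipid phosphodiesterase gene Smpdl3b rose by 1.67 and 1.79. Bone sialoprotein Ibsp was lower in both backgrounds (-1.33 and -1.73), as were the lectin Chodl (-1.43 and -0.99) and the matrix gene Matn4 (-0.98 and -0.93).

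By limma, Smpdl3b was the only gene past the threshold for c-Myc (mean 1.73, SE 0.120, Benjamini-Hochberg adjusted p = 0.0386), with 1861 genes at unadjusted p under 0.05. The model takes 1 spread from both sets. In the OSKM set 612 genes departed from additivity by at least 2-fold, against 30 in the set without OSKM. The fit on the 4 arrays without OSKM called 709 genes (550 up, 159 down), and the fit without any one of these arrays called 0. In those last fits the effect is 1 array against 1, and its spread comes only from the arrays with OSKM. Without the empty-vector or the c-Myc array 396 genes, and without the Jarid2 or the combined array 721 genes, had an unadjusted p under 0.05. Adjusted over the list alone, limma called 25 of the ribosome biogenesis genes, 24 of the cell cycle genes, 4 of 10 DNA methylation enzymes (Uhrf1 1.06 and 0.87) and 3 of 13 glycolysis genes, all up, against 0 of each over all genes. In both backgrounds 199 genes were at least 1.5-fold higher and 34 lower, where independent lists would share 7.76 and 1.13. Across genes the 2 backgrounds correlated at 0.508, and genes are not independent replicates. Of the other lists, 3 of 15 ERK feedback genes, 1 epithelial gene, 1 PRC2 gene, 1 trophoblast gene and 1 transgene were up and 1 inflammatory gene was down adjusted over the list alone, with 0 over all genes, and no gene of the remaining lists passed in either count.

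With wild-type Jarid2, few genes were far from their level without it at day 3. The ranking and counts below leave out the Jarid2 probe set that showed the transgene (higher by 3.71 without and 2.80 with c-Myc). The Jarid2 probe set used for the gene differed by -0.15 and -0.16. With a single probe set per gene, the largest difference held in both backgrounds was that of the proto-oncogene Mycn (-1.16 without and -1.23 with c-Myc). Its probe set stood at 13.61 with empty vector, far above its 7.60 and 7.11 in the clones. Whether this probe set reports Mycn alone was not tested. The phospholipid phosphatase-related gene Plppr1 (-1.0 and -0.85), the kinase Nrk (-0.98 and -0.72), the adipogenic receptor Pparg (-0.68 and -0.60) and the imprinted gene Mest (-0.67 and -0.54) were lower in both backgrounds. Higher in both were Tdrd12 (1.08 and 0.55), the antiviral helicase Ddx60 (0.56 and 0.83), Gbp3 (0.54 and 0.88) and the homeobox gene En2 (0.60 and 0.54). Tdrd12 and En2 lie near background, under 5.21, on all 4 of these arrays, as do Ddx60 without Jarid2 (4.88 and 4.82) and Plppr1 with it (4.31 and 4.06), so their differences are uncertain. In 7 genes the difference was at least 1.5-fold lower in both backgrounds, in 0 genes higher, where independent lists would share 0.16 and 0.13.

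limma called 0 genes for Jarid2 (319 at unadjusted p under 0.05). With every probe set on its own, that of the transgene included, it also called 0. The smallest Benjamini-Hochberg adjusted p in limma was 0.517, that of Mycn. A trended prior and the fit on the 4 arrays without OSKM each called 1 gene, Mycn, with limma adjusted p = 0.0301 and 0.0484. The 2 backgrounds correlated at 0.009 across genes. In the lists nothing passed over all genes. Adjusted over the list alone, limma called 2 of 6 adipocyte genes down (median -0.28) and the germline gene Tdrd12, near background, up, and none in the others. Of the developmental regulators bound by Polycomb, 0 of 45 reached 1.5-fold in both backgrounds, with a median of 0.02.

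With PrEsS next to OSKM, several pluripotency genes that were in none of the viruses rose within 3 days. Nanog rose by 4.96 without and 4.30 with the Jarid2 mutant, Nr0b1 (Dax1) by 3.98 and 3.5, Zfp42 by 3.22 and 2.98 and Tdgf1 by 2.92 and 3.25. Without PrEsS all 4 lie near background (Nanog 3.48 and 3.58, Nr0b1 3.16 and 3.33), so these sizes may be lower bounds. The same holds for other genes that start or end there, such as Qrfpr and Agmo. In the pluripotency list 7 of 35 genes rose and 1 fell (8 and 3 adjusted over the list alone), with a median of 0.30 in the pair across the split and 0.07 in the within-side pair. Other large increases lay outside that list: the peptide receptor Qrfpr rose by 4.94 and 6.18, carbonic anhydrase Car2 by 4.65 and 4.97, the membrane protein Tmem255a by 4.61 and 4.16, cardiac troponin Tnni3 by 4.13 and 4.56, the proteoglycan Srgn by 4.60 and 3.77 and Fabp3 by 4.26 and 3.74. Some of the genes that were highest with OSKM alone fell with PrEsS, Sostdc1 (-2.98 and -3.49), Hbb-y (-3.15 and -3.58) and Aldh3a1 (-2.83 and -2.27). The ether lipid enzyme Agmo (-3.57 and -3.91), the interleukin-1 antagonist Il1rn (-3.05 and -2.70), the ectonucleotidase Nt5e (-2.49 and -2.60) and the homeobox gene Meox2 (-2.23 and -2.59) fell too. All of these passed limma with Benjamini-Hochberg adjusted p between 3.5e-05 and 7.16e-04, with the direction the same in both pairs of arrays.

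Among epithelial genes 6 of 25 rose and 1 fell (7 and 1 adjusted over the list alone): Cdh1 rose by 2.22 and 1.61, the tight junction genes Marveld3 by 1.85 and 2.87 and Cldn4 by 1.22 and 1.56. Of the matrix list 9 of 25 fell (1 up and 14 down adjusted over the list alone), such as the fibroblast protease Fap (-1.40 and -1.34) and Lum (-1.74 and -1.17), and 3 of 20 mesenchymal regulators fell (4 adjusted over the list alone; Zeb2 -1.02 and -0.75). Of the ERK feedback genes 9 of 15 rose (10 up and 1 down adjusted over the list alone, medians 0.53 across the split and 0.565 within a side), with Phlda1 up by 2.42 and 1.94 and the ETS factor Etv4 by 1.45 and 1.23, in medium that held a MEK inhibitor. Of 13 glycolysis genes 5 rose (7 adjusted over the list alone), led by the pyruvate dehydrogenase kinase Pdk1 (1.60 and 1.80). The chemokine Ccl20 (3.08 and 2.20) and Mmp10 (1.28 and 0.88) were the 2 of 19 inflammatory genes that rose (4 up and 1 down adjusted over the list alone; medians 0.62 across the split and 0.08 within a side). Of 22 interferon genes limma called only Bst2 (-1.70 and -1.85) down (1 adjusted over the list alone). In the mean of both pairs 17 were lower by any amount (median -0.386). The list differed in direction between the pairs: the median was 0.53 across the split, with 9 genes at least 1.5-fold higher, and -1.44 within a side, with 18 lower.

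Smaller counts came from the other lists. The contractile list had 2 up and 1 down, the same adjusted over the list alone (medians -0.435 across the split and 0.26 within a side), the developmental regulators 3 up and 5 down of 45 (4 and 6 adjusted over the list alone; Osr1 -2.20 and -1.22), and PRC2 2 up of 11, Ezh1 and Jarid2, in both counts. Among markers of other cell types, macrophage and blood genes fell in 2 of 15 (4 adjusted over the list alone; Lyz1 -1.20 and -1.25), adipocyte genes in 3 of 6 with 1 up (in both counts; Pparg -0.93 and -0.97), endothelial genes split into 2 up and 1 down of 10 (in both counts; Kdr 1.61 and 1.76, Tek -2.21 and -1.82), and 2 of 14 skeletal muscle genes rose (3 adjusted over the list alone; Tnnt1 1.87 and 2.33). In the same 2 counts, 2 of 28 ribosome biogenesis genes rose (Tfrc 1.5 and 1.1), 1 of 17 oxidative phosphorylation genes and 1 of 11 mesendoderm markers rose, and 2 of 15 endoderm markers (Dab2) and 1 of 11 neural markers (Map2) fell. The p53 list had 1 down (2 adjusted over the list alone), germline genes 1 up (3 up and 2 down adjusted over the list alone) and Wnt targets 1 up (4 up and 3 down). The genes carried by any of the viruses had 2 up (3 adjusted over the list alone). For Esrrb and Sall4 that list used probe sets with mean effects of 0.28 and 0.52, not those that showed the PrEsS viruses. No gene of the cell cycle, cholesterol, DNA methylation, keratinocyte or trophoblast lists passed, in either count. limma called 1276 genes for PrEsS (667 up, 609 down, Benjamini-Hochberg adjusted p under 0.05), and 478 genes were at least 1.5-fold higher and 422 lower in both backgrounds, where independent lists would share 53.43 and 70.03. Without the OSKM-alone array or the array with OSKM and PrEsS, the effect is that of the within-side pair with the mutant and limma called 1458 genes, and without the array with the mutant or the combined array it is that of the pair across the split and limma called 3904. Both are 1 array against 1, with a spread taken only from the arrays without OSKM, so neither count is a replicate check. The fit on the 4 OSKM arrays called 604.

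The Jarid2 mutant next to OSKM went with opposite differences of interferon genes in its 2 backgrounds. The pair next to OSKM alone crosses the 3′ to 5′ split, and the pair next to PrEsS lies within a side. Next to OSKM alone the interferon list was higher by a median of 1.24, with 15 of 22 genes at least 1.5-fold higher, and next to OSKM with PrEsS it was lower (median -0.74), with 15 genes lower. Oasl2 differed by 2.77 and -2.54, Usp18 by 2.49 and -1.94, Ifit1 by 2.32 and -2.10 and Cxcl10 by 2.57 and -1.75. Bst2 was lower in both (-1.26 and -1.42). Of 28 ribosome biogenesis genes 23 were lower by any amount next to OSKM alone and 28 next to PrEsS, 6 and 4 of them by at least 1.5-fold (medians -0.25 and -0.50), such as the nucleolar proteins Fbl (-0.90 and -0.66) and Nolc1 (-0.96 and -0.57). Inflammatory genes were higher by any amount in 17 of 19 in each pair, and by at least 1.5-fold in 11 and 2 (medians 0.69 and 0.28, Lcn2 2.30 and 0.67, Ccl20 1.47 and 0.59). Lcn2, Ccl20, Saa3 and Ccl2 were at least 2-fold higher with PrEsS and no mutant too, compared with OSKM alone and every array without OSKM. Their differences next to OSKM alone are therefore not particular to the mutant. Cell cycle genes were lower by any amount in 25 of 26 next to PrEsS, 1 by at least 1.5-fold (median -0.30), but went both ways next to OSKM alone, 12 higher and 14 lower, 3 of these by at least 1.5-fold (median -0.17). All 25 matrix genes were higher by any amount next to PrEsS, 0 by at least 1.5-fold (median 0.34, Fap 0.56), against 15 higher and 10 lower next to OSKM alone, 1 each way by at least 1.5-fold (median 0.13).

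**Figure D4:**
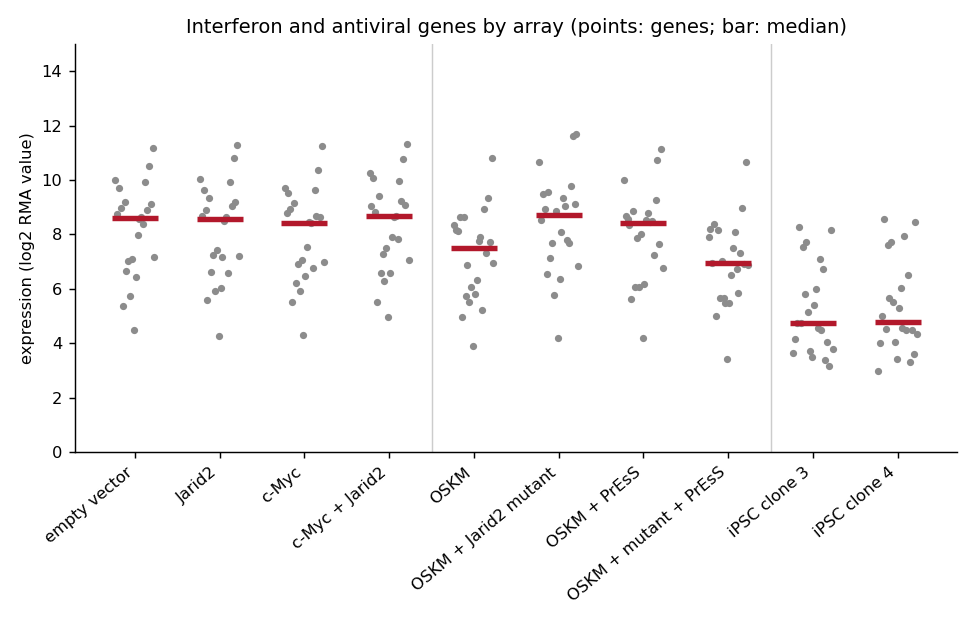
Expression (log2 RMA value, vertical axis) of the 22 measured interferon and antiviral genes on each of the 10 arrays (horizontal axis), with a point per gene and a bar at the median. The median is 7.52 with OSKM alone, 8.70 with the Jarid2 mutant, 8.41 with PrEsS and 6.93 with both, and 8.44 to 8.66 on the 4 arrays without OSKM.

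The genes with the largest difference kept in both backgrounds were the aldehyde oxidase Aox3 (1.11 and 0.93), Sptssb (1.07 and 0.86), Scg5 (0.95 and 0.76), the copper-binding ferroxidase Cp (2.34 and 0.75) and lysozyme Lyz1 (0.79 and 0.75) among the higher. Smpdl3b (-0.82 and -1.0), the folate carrier Slc19a1 (-0.84 and -0.80), carbonic anhydrase Car12 (-0.75 and -1.19), Rrp1b (-0.70 and -0.72) and Ydjc (-0.65 and -0.87) were among the lower. limma called 0 genes for the mutant over all arrays (2216 at unadjusted p under 0.05, and 0 also with a trended prior, on all 10 arrays and on the 4 OSKM arrays). The smallest Benjamini-Hochberg adjusted p of limma was 0.295. Adjusted over the list alone, limma called 13 of 28 ribosome biogenesis genes and 2 of 26 cell cycle genes down, 11 of 19 inflammatory, 2 of 25 matrix, 2 of 11 neural, 2 of 15 macrophage and blood genes and 1 of 6 adipocyte genes up, and Bst2 of the interferon genes down. Without the OSKM-alone array or the array with the mutant, the effect is that of the within-side pair with PrEsS, and limma called 19 genes (17 down, 2 up), among the lower Oasl2, Iigp1, Ifit1, Usp18 and Rtp4, named after their values were seen. Without the array with PrEsS or the combined array, it is that of the pair across the split and limma called 2304. Both are 1 array against 1, with a spread taken only from the arrays without OSKM, so neither count is a replicate check. In both backgrounds 37 genes were at least 1.5-fold higher and 16 lower, where independent lists would share 10.23 and 7.39.

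The mean effects of the wild-type Jarid2 (without OSKM) and of the mutant (with OSKM) correlated weakly across genes (Pearson 0.038, Spearman 0.048), and genes are not independent replicates. Of the 7 genes lower with wild-type Jarid2 0 were among the 16 lower with the mutant, where independent lists would share 0.006. In both backgrounds 0 genes were higher with the wild type, by the probe set used for each gene. Each effect also correlated little with itself between its 2 backgrounds (0.009 for the wild type, 0.086 for the mutant). These values therefore cannot tell whether wild type and mutant act alike. These effects were measured in different sets and share no array. With the within-side pair alone, Pearson's coefficient was 0.022 and Spearman's 0.042.

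Mutant and PrEsS together against OSKM alone gave 486 genes at least 2-fold higher and 422 lower, without a test. Among the largest increases were Qrfpr (5.51), the adhesion gene Mpzl2 (5.38), Srgn (5.12), Tmem255a (5.0), Car2 (4.94), Bex1 (4.85) and Nanog (4.4). Agmo (-3.64), Tcaf2 (-3.48), Cdkn2a (-3.23), the prefoldin subunit Pfdn2 (-3.19), Bst2 (-3.11) and the histone deacetylase Hdac8 (-2.96) were among the lowest. This pair crosses the 3′ to 5′ split. Cdkn2a, Pfdn2 and Hdac8 were also low with the mutant alone and PrEsS alone: Cdkn2a stood at 10.61 with OSKM alone and at 7.42, 7.42 and 7.38 on the other 3 OSKM arrays.

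In the first set (Jarid2 with c-Myc) 30 genes departed from additivity by at least 2-fold, led by Cxcl10 (2.86) and Cmpk2 (1.60) on the high side and by Ranbp17 (-1.47) and Arid3b (-1.38) on the low side. Ranbp17 and Arid3b are near background on these arrays (at most 5.34 and 5.17), so their departures are uncertain. In the second set (the mutant with PrEsS) 612 did, but only this set crosses the 3′ to 5′ split. On the 3 OSKM arrays across the split, 126 genes lay at least 2-fold beyond all 5 other MEF arrays, and 113 of these are among the 612. Those genes were chosen to differ from the OSKM-alone array on all 3, which nearly forces a departure. The overlap is therefore no evidence about the cause, and most of the 612 genes lie outside it. The positive departures were led by Hdac8 (3.5), Pfdn2 (3.22) and Cdkn2a (3.15), and the negative ones by the interferon genes Oasl2 (-5.31), Usp18 (-4.43), Ifit1 (-4.42), Cxcl10 (-4.31) and Iigp1 (-4.26). With 1 array per mix, a set has no spread of its own for these departures, and they were not tested.

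The 915 iPSC-high and 1429 MEF-high genes measure how far each mix had moved towards the clones. With OSKM alone the median difference from empty vector was 0.42 in the iPSC-high genes and -0.48 in the MEF-high genes. An unchanged array simulated against the same empty-vector array gave 0.02 and -0.01. c-Myc alone gave 0.23 and -0.16, and Jarid2 alone 0.007 and -0.005. As a share of the distance from empty vector to iPSC, the median iPSC-high gene had covered 14.5% with OSKM, 16.3% with OSKM and the mutant, 29.7% with PrEsS and 24.3% with both. MEF-high genes had covered 13.3%, 11.8%, 25% and 18.6%. The last 3 mixes lie across the 3′ to 5′ split from the empty vector. With PrEsS the shift was 0.34 and -0.46 next to OSKM alone and 0.11 and -0.21 in the within-side pair with the mutant. With the mutant it was 0.05 and 0.02 next to OSKM alone, and -0.13 and 0.25 in the within-side pair with PrEsS. Among matched random lists the medians lay at or beyond percentile 98.66 or at percentile 0.00, even that of -0.005, except the iPSC-high median with Jarid2 alone (percentile 28.44).

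**Figure D5:**
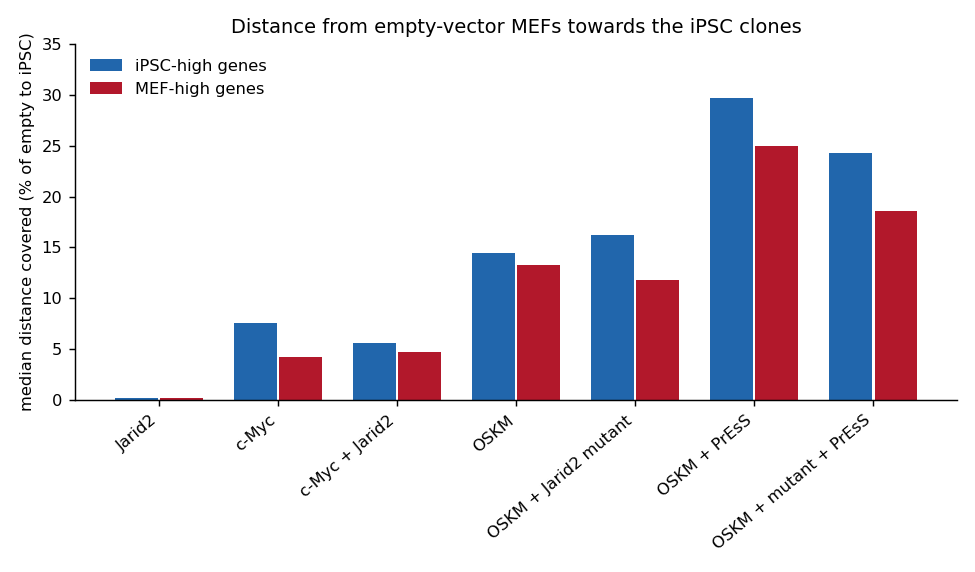
Share of the log2 distance from the empty-vector array to the iPSC clones (%, vertical axis) covered by the median iPSC-high gene (left bars) and the median MEF-high gene (right bars) on each of 7 MEF arrays (horizontal axis). The highest bars are those of OSKM with PrEsS, at 29.7% and 25%.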

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

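The tests of RNA preparation, of c-Myc activity and of the preparation difference behind the interferon genes were chosen only after the results were seen, and those of single probe sets and of immune cells before, with the floor applied to the latter only afterwards. The interferon list differed in opposite directions with the Jarid2 mutant, by a median of 1.24 next to OSKM alone (across the 3′ to 5′ split) and of -0.74 next to OSKM with PrEsS (within a side). It stands out because the same contrast runs opposite ways in its 2 backgrounds, as that of PrEsS does on the same arrays (0.53 without the mutant, across the split, and -1.44 with it, within a side); this difference was not tested, since with 1 array per mix the OSKM set has no spread of its own for it. In 23 genes, among them Oasl2 (2.77 and -2.54), Usp18 (2.49 and -1.94) and Gbp3 (2.30 and -1.75), both differences reached 2-fold.

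The combined mix and PrEsS lie on the same side of the preparation difference that sets 3 OSKM arrays apart from OSKM alone. Their interferon genes still differ by -0.74. A difference shared by these arrays cannot separate them, but they were put on the same side by the beta-actin value. The limit for this test was also set after the difference was seen, so it does not decide about preparation. Immune cells cannot be told apart: the macrophage and blood list was not lower (median 0.18, 12 of 15 higher by any amount, Lyz1 6.73 and 7.48, but Mpeg1 5.78 and 5.16), yet most members are near background (median levels 4.65 and 5.0, floor 5.21) and there is no replicate. An interaction of the mutant with PrEsS, another difference in preparation, or a difference between 2 single samples, stays open and untested.

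The 3 OSKM arrays with the mutant, PrEsS or both stand apart alike, with 88 genes at least 2-fold below and 38 at least 2-fold above all 5 other MEF arrays on each of the 3. The largest number for any other choice of 3 of the 8 MEF arrays was 3 genes, out of 56 choices. The beta-actin 3′ minus 5′ value of the 3 lies 0.395 above the highest of the other 5, whose range is 0.101. This goes with RNA of different integrity or preparation, but the same value was used to define the sides. In the clones it is higher still (1.30 and 1.28), yet these genes did not all follow it. Pfdn2 stood at 9.46 and 9.33 in the clones and at most at 7.24 on the 3 arrays. Hdac8 was low in the clones (4.26 and 4.26) and on the 3 (4.22 to 4.51). The clones are another cell type, so their levels do not decide the cause. Whether the labelling of single probe sets adds to the split cannot be told apart. The change of other probe sets relative to the chosen one had a median ratio of 0.621 in these genes and 0.973 in reference genes. The quotient of 0.639 (bootstrap 0.403 to 0.794) lies between the bounds set for the 2 answers, in the 24 of 126 genes that could be measured. In 6 of the 24 the other probe sets moved under 0.25 times as much as the chosen one, against 0 of 65 reference genes. A response shared by the mutant and PrEsS stays open.

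Growth genes were lower with the Jarid2 mutant next to PrEsS. The 199 genes at least 1.5-fold higher with c-Myc in both backgrounds had a median of -0.425 in this pair (194 lower by any amount) and -0.284 next to OSKM alone (143 lower), each at percentile 0 among matched random lists; without the 17 that belong to the growth list the medians were -0.407 and -0.279, also at percentile 0. This is consistent with weaker c-Myc activity but does not separate it from any other cause that lowers growth genes, and the Myc probe set was lower in the first pair (8.92 and 8.63) and higher in the second (8.53 and 8.63). RNA preparation cannot be told apart: the beta-actin value differs by only -0.062 between these arrays, but they were put on the same side of the split by that value, so it decides nothing. An effect of the mutant itself and a difference between 2 single samples stay open, untested.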

How the results depend on the processing

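The reference arrays for the clones other than empty vector, and the set choice against the Jarid2 array, were tried only after the results were seen. Of the values answering a comparison, 183 under an alternative were within the stated limits and 52 moved, with 0 reversed; of single genes and lists, 4802 and 287, with 1 reversed. That one is Ndufb8 in the clones (-0.916 with the mean of its probe sets). The cause was not tested except where stated. No paired analysis was possible because each MEF group holds 1 array, so that no 2 groups share more than a single replicate number. Dim genes limit what can be measured, since array signal near background hides differences.

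Jarid2 calls became 1 with a trended prior and 1 on its own 4 arrays. c-Myc calls became 0 with quantile normalization, 0 with dim genes left out, 0 with every probe set on its own, 2 with a trended prior, 25 on all 10 arrays and 709 on its own 4 arrays; without any one array of its set they were 0. Jarid2 mutant calls ranged from 19 to 2304 when one array was left out. PrEsS calls were 604 on its own 4 arrays and 1458 to 3904 with one array left out: for both factors the low end is without the OSKM-alone array (or, with the same value, its partner with the factor alone), and the high end without the combined array or the array with the other factor. In each fit without an array, the effect is 1 array against 1 and the spread comes only from the other set of MEF arrays, assumed to vary alike. The clones' calls became 16209 with every probe set, which tests more features.

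Genes past 1.5-fold in both backgrounds became, with every probe set on its own, 13 (Jarid2), 360 (c-Myc), 97 (mutant) and 1403 (PrEsS); at 2-fold 1, 14, 1 and 358; and with the mean of probe sets 150 (c-Myc) and 30 (mutant). Genes past 2-fold became, with every probe set, 10425 (clones), 1414 (OSKM), 1655 (combined mix), 69 (departure, Jarid2 and c-Myc) and 1304 (departure, mutant and PrEsS). At 3-fold they were 3562, 252, 278, 2 and 136, and at 1.5-fold 2654 (OSKM), 2723, 475 and 2393. With the mean of probe sets the departures were 19 and 377. The additive limma model, which also draws on the OSKM arrays across the split, called 2020 genes for OSKM. More features or another threshold change these counts by construction.

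With OSKM the iPSC-high shift was 0.282 with the mean of probe sets and 0.294 with genes at least 8-fold apart, and the MEF-high shift -0.601 with the latter. With genes at least 8-fold apart the combined mix against OSKM alone gave 0.287 in iPSC-high genes, and PrEsS beside the mutant -0.337 in MEF-high genes.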

Other observations

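The correlations across genes and the genes with opposite differences were chosen only after the results were seen. Values of further lists between OSKM and empty vector at day 3 follow. Of the DNA methylation genes 3 of 10 were at least 1.5-fold higher and 0 lower (median 0.30), such as Uhrf1, which guides maintenance methylation (1.48), and the de novo methyltransferase Dnmt3b (1.09). PRC2 genes had a median of 0.21 with 1 of 11 higher, and the developmental regulators bound by Polycomb a median of -0.11 with 6 of 45 lower. Oxidative phosphorylation genes had a median of 0.31 (2 of 17 higher) and cholesterol biosynthesis genes of 0.24 (1 of 13 higher). Among lineage and germline groups the medians were -0.22 for endoderm, 0.01 for mesendoderm, 0.03 for neural and 0.00 for germline genes. Inflammatory genes had a median of -0.16, with 4 of 19 lower, Wnt targets of 0.08 and p53 genes of -0.01. Markers of other cell types had medians of 0.04 for keratinocytes, -0.10 for endothelium, -0.22 for skeletal muscle, -0.01 for adipocytes, 0.01 for trophoblast and -0.17 for macrophages and blood.

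Without OSKM, the chemokine Cxcl10 differed in opposite directions. With Jarid2 it was lower alone (-1.80) and higher beside c-Myc (1.06), and with c-Myc it was lower alone (-1.60) and higher beside Jarid2 (1.26), in 1 array each. These differences share arrays. It was the 1 gene of either factor with opposite differences of at least 2-fold. PrEsS gave 14 such genes, including Oasl2 (1.95 and -3.36) and Ifit1 (1.65 and -2.78).

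Across genes, the c-Myc effect beside Jarid2 and the difference of OSKM from empty vector, which share no array, correlated at 0.391. The mean c-Myc effect correlated with the Jarid2 mutant difference next to PrEsS at -0.429 and next to OSKM alone at -0.123. The difference of the clones from empty vector correlated with the PrEsS difference in the within-side pair at 0.271 and with the mutant difference in the within-side pair at -0.361. Genes are not independent replicates.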
